A study of Mus musculus with 2 samples.

How the data were processed

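Small RNA libraries were made from total RNA of gastrocnemius, the large superficial calf muscle, of female mice aged 14 days of the strain B6CASTF1/J, a first-generation cross of C57BL/6J and CAST/EiJ. The labels give 1 group with 2 biological replicates, numbered 1 and 2, and select RNA shorter than 30 nt. The biosample name of replicate 1 mentions 3 females and that of replicate 2 a single female. Both carry the same donor identifier, per the labels, although they are numbered as separate biological replicates with separate biosamples. Nothing in the labels says whether RNA was pooled, so the SD between replicates covers whatever differs between these samples. No treatment, second tissue or second age is named, so levels were described and no groups were compared.

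The deposited values are raw read counts per microRNA gene. Each library's file has 3 count columns, taken from their order as reads counted without regard to strand, reads on the strand of the gene and reads on the opposite strand. The deposited counts were made on the mm10 assembly with GENCODE release M21, per the file headers. The aligner and counter are not given in the sources used here, although the 4 summary lines and the column order are those of STAR's gene counts. In that layout a read aligned to several places adds to no gene and appears only in the total of multiply aligned reads. Each gene's count pools both arms of its hairpin, so a mature strand and its partner strand cannot be told apart.

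The same-strand column was used throughout, because adapter ligation of small RNA keeps the strand. In that column no read was ambiguous between genes, whereas the unstranded column left 708973 reads in replicate 1 and 1064808 in replicate 2 ambiguous. All 2202 gene identifiers matched the GENCODE M21 annotation, which supplied symbols, positions, hairpin sequences and the genes that overlap each hairpin on the same strand. The 4 lines that name no gene (unmapped, multiply aligned, outside genes, ambiguous) held 66.6% of reads in replicate 1 and 64.6% in replicate 2, and stayed out of all totals.

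Counts were divided by the library's total over microRNA genes to give CPM, the usual unit in which every library has the same total. These totals were 2672454 in replicate 1 and 4292012 in replicate 2, so 1 read was worth 0.374 CPM and 0.233 CPM. A gene with no read had an upper limit of 1.12 CPM in replicate 1 and 0.699 CPM in replicate 2, taking 3 reads as the limit. A gene was called expressed at 1 CPM or more in both replicates. Shares have exact (Clopper-Pearson) 95% binomial intervals, and ratios between the replicates have intervals derived from them. The labels name no molecular identifiers, so these intervals and limits cover counting error only.

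The spread between replicates beyond counting error was summarised as edgeR's common dispersion (edgeR 4.0.16 in R 4.3.3, TMM factors, genes at 10 CPM or more in both replicates), whose square root is the biological coefficient of variation. With 1 group there was no test between groups, and the only p-values are from permutation tests across genes in the closing observations. The script was tested on simulated data with the real means and library totals of all 2202 genes. Coefficients set to 0.1, 0.2 and 0.4 came back as 0.0984, 0.195 and 0.390. When 200 genes below 10000 CPM were changed 4-fold up or down in replicate 2, with the measured coefficient, 42 of the 45 that had 100 CPM or more passed a 2-fold limit, as did 3 of 129 unchanged genes.

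Before the data were examined, 17 gene lists (muscle, imprinted and other clusters, families, and markers of other cell types), 31 sets of genes known to encode the same mature microRNA and the rule for named genes were fixed. The rule named the 20 most abundant genes, the 4 most abundant of each list with all myomiR, erythroid and H19-Igf2 members, the 5 genes farthest apart in each direction between the replicates at a mean of 100 CPM or more, and partners of named copies. Of the list entries, Mirlet7j, Mirlet7k and Mir193 had no gene of that name. Mir496b, entered in the Dlk1-Meg3 list, lies on chromosome 19 and had 0 reads. For 12 lists with at least 3 members at a mean of 10 CPM, the median log2 ratio of replicate 2 over replicate 1 was placed among 10000 random lists of the same size matched on mean CPM. This percentile describes these 2 libraries and is not a p-value.

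Alternatives covered the strand column, TMM and DESeq2 1.42.0 size factors, the CPM thresholds, sums over identical copies, other denominators and each replicate alone. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Correlations used log2 values of CPM plus a pseudocount of 1. The accompanying text files describe the deposit and hold no measurements.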

Results

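microRNA levels were measured by small RNA sequencing in gastrocnemius muscle of 14-day-old female mice of a C57BL/6J by CAST/EiJ cross, in 1 group of 2 biological replicates. Replicate 1 held 8002643 reads, of which 2672454 (33.4%) were assigned to microRNA genes, and replicate 2 held 12134412, of which 4292012 (35.4%) were assigned. Reads that aligned to several places made up 52.7% and 52.4% of the libraries and were assigned to no gene. All levels are CPM of the assigned same-strand counts, as mean ± SD (n = 2), and all coordinates are mm10. The first question was which microRNA genes made up the small RNA pool of this young muscle.

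Of 2202 annotated microRNA genes, 367 reached 1 CPM in both replicates. The assigned counts were dominated by few genes. The 10 most abundant held 61.4% ± 1.15 of counts, and 69 genes with a mean of 1000 CPM or more held 95.5%. These ranks hold among reads assigned to 1 gene, and microRNAs with identical copies, Mir1a and Mir133a among them, may rank higher. The most abundant by these counts was Mir126a, the endothelial microRNA carried by Egfl7 (chromosome 2, 26591357 to 26591429, within an annotated Egfl7 exon), at 11.9% ± 0.0385. Mir378a, in an intron of Ppargc1b, a coactivator of mitochondrial genes (chromosome 18, 61397835 to 61397900), followed at 10.7% ± 1.17. Mir206, a microRNA largely restricted to skeletal muscle, came next at 8.99% ± 0.736. Mir127, of the imprinted Dlk1-Meg3 cluster, held 6.69% ± 0.548. The let-7 genes Mirlet7g (5.02% ± 0.314) and Mirlet7i (4.76% ± 0.0673), Mir23b (4.11% ± 0.0948), Mir411 (3.35% ± 0.648), Mir23a (3.09% ± 0.270) and Mir22 (2.79% ± 0.595) completed the first 10.

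The next 10 genes ranged from 9951 CPM for Mir30d to 20377 CPM for Mir26b. They were, in falling order, Mir26b, Mir143, Mir379, Mirlet7b, Mir99a, Mir487b, Mir139, Mir335, Mir431 and Mir30d. Mir26b lies in an intron of Ctdsp1, Mir139 in an intron of Pde2a and Mir335 in an intron of Mest, an imprinted gene. Mir335 stood at 12374 ± 603 CPM and Mir139 at 12762 ± 1252 CPM.

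**Figure D1:**
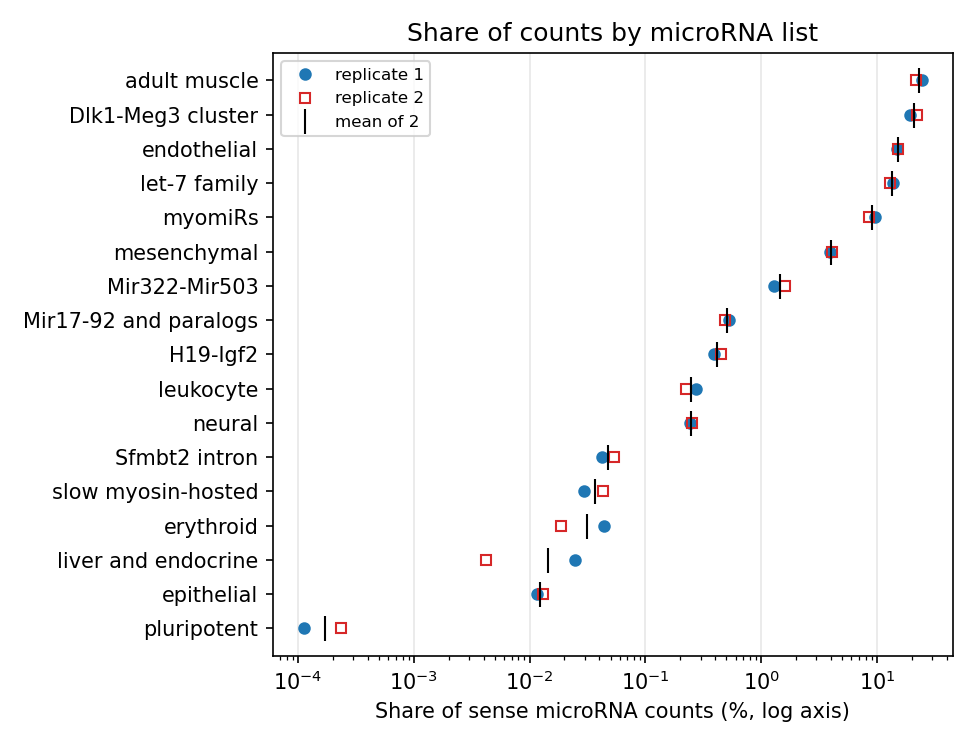
Share of same-strand microRNA counts (percent, log axis) held by each fixed gene list, with circles for replicate 1, squares for replicate 2 and bars for their mean. The adult muscle, Dlk1-Meg3, endothelial and let-7 lists each held over 10% of counts, and the liver and endocrine list was 5.96 times higher in replicate 1.

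The striated muscle microRNAs (myomiRs) held 9.11% ± 0.738 of counts, and nearly all of it was Mir206. Of 13 listed genes, 10 were expressed. Mir206 lies at chromosome 1, 20679010 to 20679082, within an exon of the long noncoding gene Gm28653, and its hairpin reads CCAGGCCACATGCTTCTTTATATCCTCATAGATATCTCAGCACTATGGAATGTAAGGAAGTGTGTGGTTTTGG. It stood at 89900 ± 7361 CPM. Mir486, in an intron of Ank1 and abundant in muscle and red cells, had 591 ± 74.3 CPM, and Mir3107, on the opposite strand of the same locus, 13.3 ± 2.34 CPM. Mir486 and Mir3107 overlap on opposite strands over 90 nt. A stretch of 22 nt, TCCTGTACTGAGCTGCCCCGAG, occurs on both strands of the hairpin, so both read counts are lower bounds. Mir1a-2 had 207 ± 53.2 CPM and Mir1a-1 8.24 ± 0.539 CPM. Mir133b had 28.2 ± 3.92 CPM, Mir133a-1 3.08 ± 0.404 CPM and Mir133a-2 1.42 ± 0.954 CPM, and Mir1b and Mir133c had at most 3 reads in a library.

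Reads shared between copies bear directly on these values. Mir1a-1 and Mir1a-2 share the stretch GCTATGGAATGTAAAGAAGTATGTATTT of 28 nt, and Mir133a-1 and Mir133a-2 share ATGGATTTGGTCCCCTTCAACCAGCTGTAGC of 31 nt. Mir133b shares 21 nt, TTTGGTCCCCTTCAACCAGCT, with both. A read within such a stretch fits more than 1 locus and would be counted among the multiply aligned reads. The read counts of Mir1a and Mir133a genes are therefore lower bounds on their microRNAs. Multiply aligned reads numbered 1.58 per assigned read in replicate 1 and 1.48 in replicate 2, and they stayed out of the totals too. Placing them could raise or lower the CPM and share of any gene. The longest stretch that Mir206 shares with Mir1a-1 is 13 nt. Among expressed list members, 39 genes of the fixed copy sets had a median of 37.7 CPM and 134 genes outside those sets a median of 428 CPM. The 134 were not chosen by sequence, so some may share stretches with other loci. All 64 genes of the copy sets together held 1.19% of counts.

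**Figure D2:**
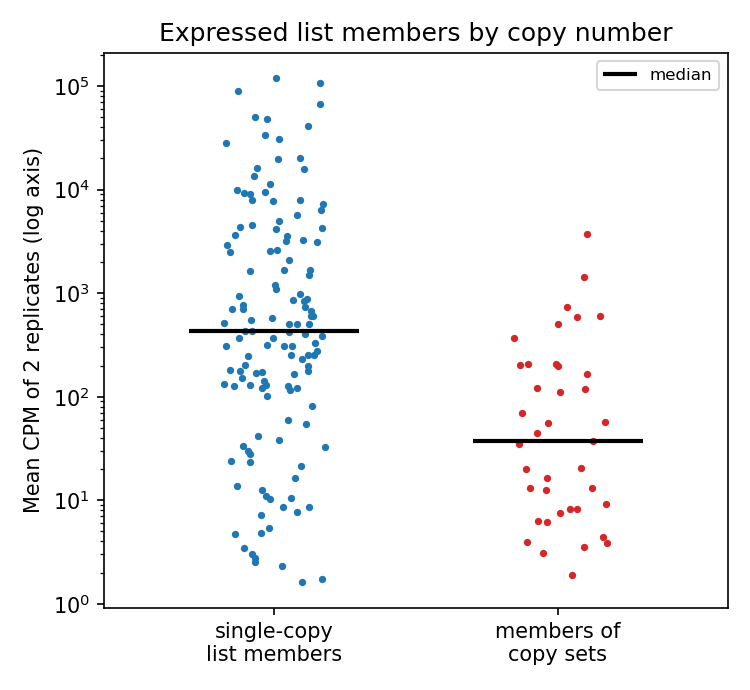
Mean CPM of the 2 replicates (log axis) for expressed members of the fixed lists, each point being a gene and the bars the medians. The 39 members of sets with identical mature copies have a median of 37.7 CPM, against 428 CPM for 134 genes outside those sets. These 134 are labelled single-copy but were not chosen by sequence.

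Genes hosted by slow or cardiac myosin heavy chain introns held 0.0364% ± 0.00966 of counts. Mir499, in Myh7b, had 246 ± 47.3 CPM, and Mir208b, in the slow-fibre myosin gene Myh7, had 115 ± 47.6 CPM. Mir208a, in the cardiac gene Myh6, had 2.31 ± 1.68 CPM, from 3 and 15 reads. Both Mir499 and Mir208b were higher in replicate 2, by 1.31-fold (95% counting interval 1.19 to 1.45) and 1.83-fold (1.56 to 2.14).

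The imprinted Dlk1-Meg3 cluster, whose microRNAs are made from the maternal chromosome, was the largest single genomic source of counts among the fixed clusters. Its 58 genes, which span 184 kb of chromosome 12 from 109563692 (Mir770) to 109747960 (Mir3072), held 20.8% ± 1.99 of counts. Of the 59 listed genes, 53 were expressed and 45 had a mean of 100 CPM or more. Mir127 (66856 ± 5476 CPM), Mir411 (33509 ± 6483 CPM), Mir379 (16014 ± 986 CPM) and Mir487b (13449 ± 1701 CPM) were the highest. Mir431 stood at 11374 ± 1607 CPM. The H19-Igf2 region, another imprinted growth locus, held 0.418% ± 0.0396 of counts. Mir483, in an intron of Igf2, had 4149 ± 397 CPM. Mir675, in an exon of H19, had 30.1 ± 0.773 CPM.

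**Figure D3:**
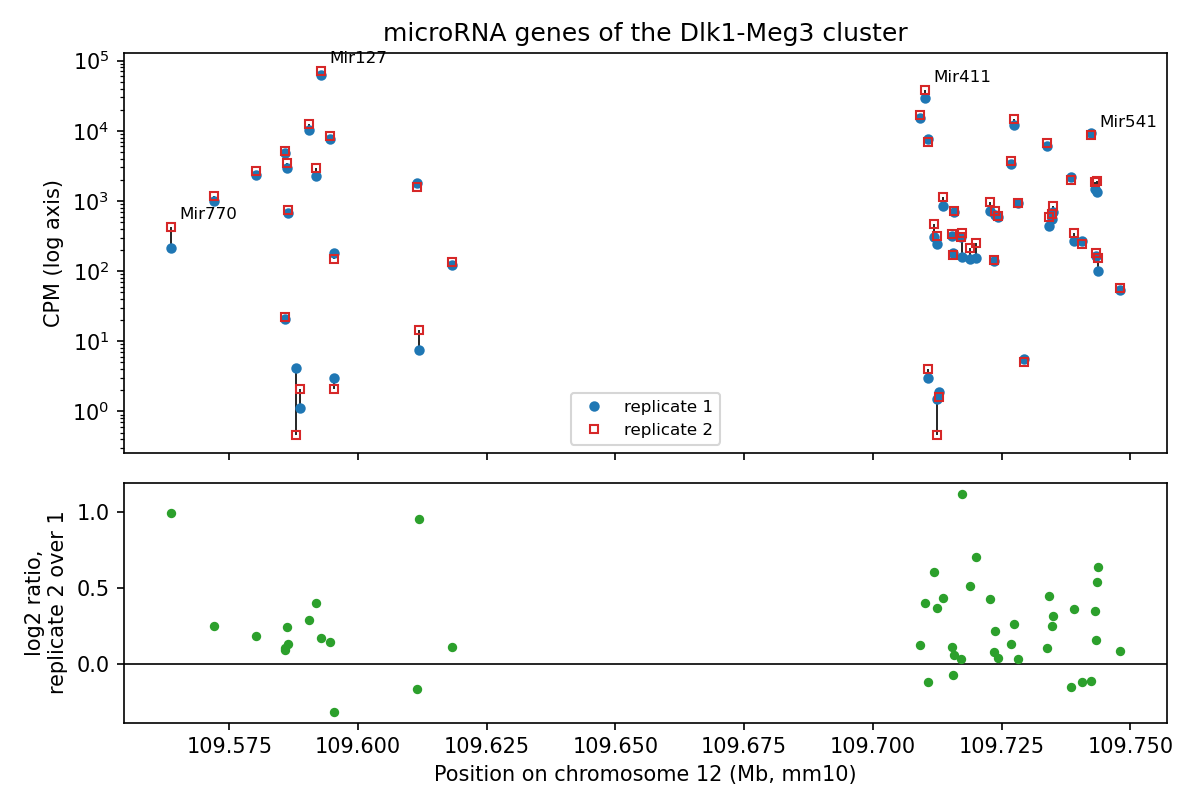
Levels of Dlk1-Meg3 cluster genes with reads in both replicates, by position on chromosome 12 (Mb, mm10). The upper panel gives CPM (log axis) in replicate 1 (circles) and replicate 2 (squares), joined by lines, and the lower panel the log2 ratio of replicate 2 over replicate 1 for genes with a mean of 10 CPM or more, of which 41 of 48 lie above 0.

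All 12 annotated let-7 genes were expressed and together held 13.4% ± 0.535 of counts. By these counts this family, whose members restrain growth and developmental genes, was led by Mirlet7g, Mirlet7i, Mirlet7b (15968 ± 1159 CPM) and Mirlet7d (9339 ± 871 CPM). Mirlet7a-1 (208 ± 52.3 CPM) and Mirlet7a-2 (121 ± 16.7 CPM) share a stretch of 23 nt. Mirlet7c-1 and Mirlet7c-2 also share 23 nt, and Mirlet7f-1 and Mirlet7f-2 share 22 nt. The read counts of let-7a, let-7c and let-7f are therefore lower bounds, and these members may rank higher within the family. The list of widely expressed microRNAs abundant in adult muscle held 23.0% ± 1.78, led by Mir378a, Mir23b, Mir22 and Mir26b, with 29 of 30 annotated members expressed. The X-linked Mir322-Mir503 cluster, active in myogenic differentiation, held 1.44% ± 0.210. Mir322 stood at 9510 ± 1184 CPM, Mir351 at 3617 ± 1030 CPM, Mir542 at 854 ± 134 CPM and Mir503 at 233 ± 16.5 CPM. The growth-related Mir17-92 cluster and its paralogs held 0.504% ± 0.0284, with Mir17 at 1512 ± 34.5 CPM, Mir93 at 1200 ± 226 CPM, Mir92-1 at 730 ± 46.9 CPM and Mir20a at 550 ± 21.4 CPM. Mir92-1 shares 22 nt with Mir92-2, so its read count is a lower bound. The 14 listed genes of the Sfmbt2 intron cluster held 0.0477% ± 0.00819, led by Mir467d at 252 ± 44.3 CPM and Mir467e at 150 ± 24.8 CPM, with Mir669c at 41.7 ± 0.285 CPM and Mir467c at 32.6 ± 12.8 CPM. Of the 14, 9 had no read in either replicate. Reads that fit several genes of the cluster would enter no count, so these read counts may be lower bounds. The list covers part of that intron, and Mir669o (55.2 ± 9.86 CPM) and Mir669l (18.6 ± 3.61 CPM), chosen after their values were seen, lie outside it.

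Lists fixed as markers of cell types other than muscle fibres were measured alongside. The RNA came from whole tissue, so these shares do not show which cells held the microRNAs. The endothelial list held 15.1% ± 0.300, mostly Mir126a (11.9%) and Mir23a, with Mir27a at 435 ± 56.8 CPM and Mir24-2 at 118 ± 17.3 CPM. The related genes Mir23b, Mir27b and Mir24-1 stand on the adult muscle list. The counts of Mir23a, Mir27a and Mir24-2 therefore cannot be assigned to endothelial cells. Mir24-2 shares 28 nt with Mir24-1, so its read count is a lower bound. Fibroblast and smooth muscle markers held 3.99% ± 0.103, led by Mir143 (19812 ± 483 CPM), Mir10b (7959 ± 443 CPM), Mir21a (4512 ± 376 CPM) and Mir214 (4276 ± 328 CPM). Leukocyte markers held 0.247% ± 0.0359, led by Mir342 (874 ± 0.00897 CPM), Mir146 (582 ± 124 CPM), Mir155 (401 ± 145 CPM) and Mir150 (366 ± 68.7 CPM). Neural markers held 0.247% ± 0.00874, mainly Mir128-1 (1424 ± 112 CPM), Mir338 (508 ± 175 CPM) and Mir128-2 (369 ± 55.3 CPM), with Mir138-1 at 70.2 ± 27.9 CPM. Mir128-1 and Mir128-2 share 23 nt, and Mir138-1 and Mir138-2 share 24 nt, so the Mir128 and Mir138 read counts are lower bounds. No read fell on the 3 Mir124a genes, but those also share identical copies. Erythroid markers held 0.0311% ± 0.0178. Mir451a and Mir144 had 179 ± 102 and 132 ± 75.9 CPM, and Mir451b, opposite Mir451a, had 0 reads, which allows up to 1.12 and 0.699 CPM. Epithelial markers held 0.0124% ± 0.00104, with Mir203, Mir192, Mir194-2 and Mir205 highest. Of 14 pluripotent cell genes, none reached 1 CPM in both replicates, and the whole list had 3 reads in replicate 1 and 10 in replicate 2, most of them from Mir302d. Hepatocyte and endocrine markers held 0.0248% (95% binomial interval 0.0230 to 0.0268) in replicate 1 and 0.00417% (0.00358 to 0.00483) in replicate 2, most of the former from Mir122.

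The second question was how far the 2 replicates agreed. Across the 440 genes at 1 CPM in either replicate, Spearman's rho was 0.973 and Pearson's r was 0.989 on log2 CPM, across genes that are not independent replicates. The biological coefficient of variation was 19.6% over 255 genes at 10 CPM in both (edgeR common dispersion) and 16.4% without Mir122. The square root of the median of DESeq2's gene-wise dispersions over the 255 genes was 7.09%. Both samples carry the same donor identifier in the labels, so these values are the spread between these samples and may not be a spread between unrelated animals. Among 176 genes with a mean of 100 CPM or more, the median difference between replicates was 1.12-fold. For 130 of them (73.9%) the 95% counting interval of the ratio excluded 1, and these intervals cover counting error only. In a check for 1 library deposited again, the chi-square of the counts over the 255 genes was 147 per degree of freedom. This excludes random draws of reads from 1 library. It does not exclude 1 library run or processed in another way, or a second preparation of the same RNA. Only 4 of the 176 differed by more than 2-fold.

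**Figure D4:**
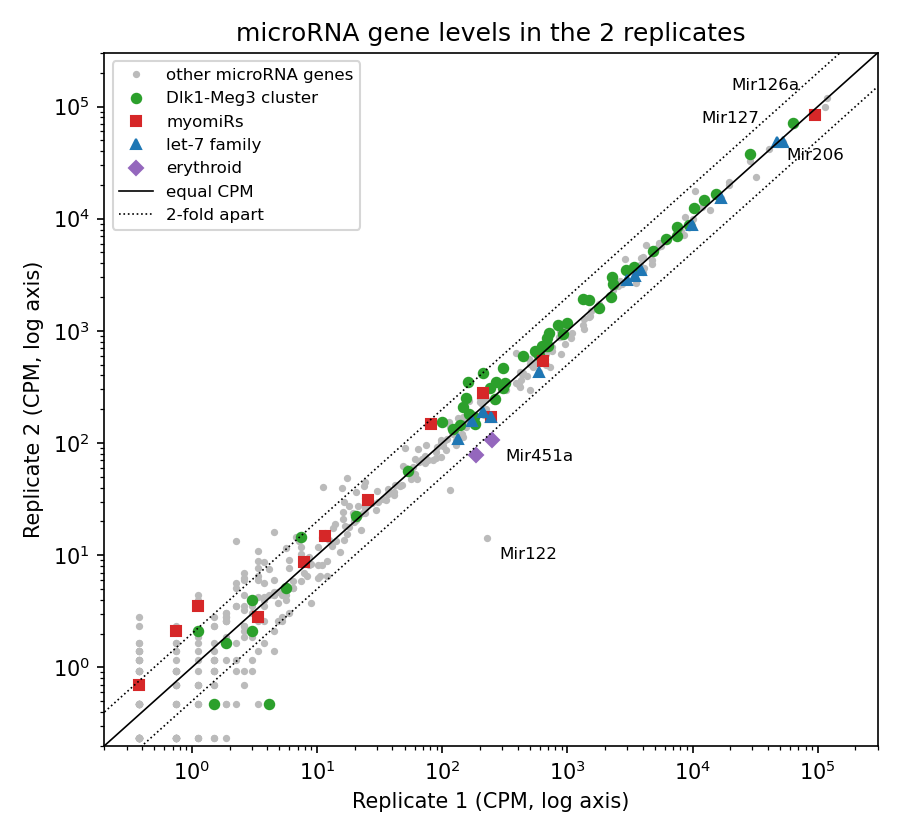
CPM of each microRNA gene with reads in both replicates, replicate 1 against replicate 2 (log axes), with 4 lists marked by colour and shape; the solid line is equality and the dotted lines are 2-fold apart. Mir122 lies farthest from equality among genes with a mean of 100 CPM or more, at 16.1-fold higher in replicate 1.

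The gene farthest apart was Mir122, the dominant microRNA of hepatocytes (chromosome 18, 65248861 to 65248926). It had 229 CPM in replicate 1 and 14.2 CPM in replicate 2, 16.1-fold higher in replicate 1 (95% counting interval 12.4 to 21.3). The erythroid genes Mir144 and Mir451a, 100 bp apart on chromosome 11, were 2.37-fold (2.06 to 2.73) and 2.35-fold (2.09 to 2.65) higher in replicate 1. Mir155, of activated leukocytes, was 1.69-fold (1.56 to 1.83) and Mir181b-2 1.51-fold (1.42 to 1.61) higher there. Mir181b-2 shares 26 nt with Mir181b-1, so its ratio rests on the reads assigned to it alone. In the other direction, Mir543 of the Dlk1-Meg3 cluster was 2.17-fold (1.95 to 2.42) and Mir770, in an exon of Meg3, 1.99-fold (1.81 to 2.19) higher in replicate 2. Mir208b was 1.83-fold higher there, Mir99a 1.69-fold (1.67 to 1.72) and Mir338, in an intron of Aatk, 1.64-fold (1.53 to 1.77). With a single library on each side these ratios compare the libraries, not animals or conditions, and no p-value was computed.

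Gene lists were also set side by side between the replicates. In the Dlk1-Meg3 list 41 of 48 members with a mean of 10 CPM or more were higher in replicate 2. Their median log2 ratio of replicate 2 over replicate 1 was 0.18, above 99.9% of matched random lists. The neural list had a median of 0.77, above 99.97% of random lists, from 6 members. Of these, Mir338, Mir138-1, Mir138-2 and Mir137 were higher in replicate 2, and Mir128-1 and Mir128-2 were lower. The 2 Mir138 genes encode the same mature microRNA, as do the 2 Mir128 genes, so the 6 members are not independent draws. The same holds for the 48 Dlk1-Meg3 members, which lie within 184 kb, and for the let-7 and adult muscle lists, which hold identical copies. The leukocyte list had a median of -0.38 (0.525th percentile), with Mir146, Mir155, Mir150 and Mir142 lower in replicate 2, Mir342 at 874 CPM in both and the interval of Mir223 including 1, and the adult muscle list a median of -0.16 (0.45th percentile), with 17 of 24 lower. The let-7 list was lower in 11 of 12 members, with a median of -0.16 at the 2.44th percentile, and with the GC trend of the other genes removed it lay at the 2.78th, inside the central 95%. The myomiR share was lower in replicate 2 (8.59% against 9.63%) because of Mir206, while the median of its 7 members with a mean of 10 CPM or more was 0.28 (90.6th percentile). The medians of this list and of the 6 not yet named among the 12 lay within the central 95% of matched random lists. TMM or DESeq2 size factors moved every log2 ratio by -0.04 and -0.03, the same shift for all genes, and the endothelial median of 0.01 lay near enough to 0 to change sign with it.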

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

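The tests of shared sequence stretches and both tests on Mir122 were chosen after the result was seen. Reads aligned to several places, which enter no gene's count, made up 52.73% of replicate 1 and 52.35% of replicate 2. Reads on the opposite strand of the 2138 genes with no gene there numbered 35 in replicate 1 and 36 in replicate 2, and no single gene passed the 3-read limit in both replicates.

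The genes with identical mature copies had low counts. Reads shared between paralogs are a candidate explanation. The median log2(mean CPM + 1) of list members outside the copy sets exceeded that of copy-set members by 3.47. This restates the pattern, since low expression of the copies would give it too. Over all expressed genes, those sharing 18 nt or more with another locus differed by -0.59 (permutation p = 0.462, two-sided), and those sharing 22 nt or more by -1.24 (permutation p = 0.166, two-sided). These tests cannot decide, because a gene that lost its reads to multiple alignment may fall below 1 CPM and leave the comparison. At 22 nt, 1032 of the 2202 genes shared a stretch, but only 67 sharing genes were expressed, against 300 others. Sharing genes held 37.2% of counts at 18 nt and 1.34% at 22 nt. Low expression of the copies and lost reads cannot be told apart, because the deposited counts do not place the shared reads, and no biological explanation was tested.

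Mir122 was 16.1-fold higher in replicate 1. Counting error was excluded, since the lower limit of the 95% counting interval was 12.4-fold. RNA from liver cells is a candidate source, but the pooled reads of Mir192 and Mir194-2, which hepatocytes also hold, stood at a ratio of replicate 1 over replicate 2 of 0.978 (95% counting interval 0.753 to 1.26). These genes had 98 and 161 reads, and the epithelial list holds them too, so the liver source cannot be told apart from others at this depth. The erythroid genes Mir144 and Mir451a were higher in the same replicate, and no biological explanation was tested.

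Of the 48 Dlk1-Meg3 members at a mean of 10 CPM or more, 41 were higher in replicate 2. Being in 1 cluster, these members are not independent draws. With the linear trend of the other genes on hairpin GC content removed, their median log2 ratio was 0.16 (99.98th percentile of matched random lists). That trend was 0.037 in log2 ratio per 10 points of GC, and median hairpin GC was 47.8% in the cluster and 50.2% in the other genes. This argues against hairpin GC content as the whole cause, but the GC content of the sequenced inserts was not tested. With the 20 most abundant genes left out of totals and list, the cluster median was 0.14 over 43 members. New totals shift every gene alike, so this test decides nothing about a few genes taking most of the counts. A difference between the samples stays open, although the labels give both the same donor identifier, and no biological explanation was tested because the design has 1 group.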

How the results depend on the processing

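The fit without Mir122 and the unstranded shares of single genes were chosen after seeing the data. Expressed genes numbered 255 to 496 under every alternative run, within 1.5 times 367. With 2 replicates, leaving out either gives the other's value: 60.6% to 62.2% for the 10 most abundant genes, 8.59% to 9.63% for the myomiRs and 19.4% to 22.2% for the Dlk1-Meg3 cluster. Unstranded counts put the 10 most abundant genes at 57.6%, the myomiRs at 12.2%, the Dlk1-Meg3 cluster at 25.8% and Spearman's rho at 0.953. That column left most reads at genes with a gene on the opposite strand ambiguous, and Mir126a held 0.00023% and Mir378a 0%, while Mir206 held 12.1% and Mir127 8.99%. With Mir126a left out of all counts, the 10 most abundant of the remaining genes held 58.5% and the myomiRs 10.3%, and without myomiRs the Dlk1-Meg3 cluster held 22.9%, by construction. Spearman's rho was 0.909 with no filter and 0.986 at 10 CPM. The coefficient of variation was 0.143 at 100 CPM in both replicates, 0.0709 from the median of DESeq2's gene-wise dispersions and 0.164 without Mir122. The 100 CPM limit also left out Mir122 and Mir144, which had 14.2 and 78.3 CPM in replicate 2. The DESeq2 value describes the median gene, whereas edgeR's common dispersion pools all genes. The cause of the difference was not tested further. Genes over 2-fold apart numbered 10 at a mean of 10 CPM and 0 at 1000 CPM, against 4 at 100 CPM. TMM and DESeq2 size factors gave the same 4 genes. No paired analysis was possible because the design has 1 group. Depth limits genes under 1.12 CPM in replicate 1 and 0.699 CPM in replicate 2.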

Other observations

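Apart from those under the naming rule, the genes named here were chosen after their values were seen, and the test without the Mir144 and Mir451a pair was chosen after the result was seen. At a mean of 10 CPM or more, 6 further genes lay over 2-fold apart between the replicates. Mir182 and Mir183, 2 genes of a cluster known from sensory cells, had 15.7 and 11.2 CPM in replicate 1 and 39.6 and 40.3 CPM in replicate 2. Mir137, of neurons, had 17.2 and 48.9 CPM, Mir205, of squamous epithelium, 6.74 and 14.4 CPM, and Mir760 4.49 and 16.1 CPM. Snord43, which the annotation lists as a microRNA gene in an intron of Rpl3, had 115 and 37.7 CPM.

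Over 33 pairs of same-strand neighbours the median difference in level was 4.39-fold, with 12 pairs over 10-fold apart. In some of these 12 the lower gene belongs to a copy set (Mirlet7f-1, Mirlet7c-2, Mirlet7c-1 and Mirlet7a-2), so lost reads may widen the difference. Some pairs were near equal, such as Mir181d and Mir181c (1.02-fold). Mir133b lies 3687 bp from Mir206 and was 3186-fold lower, but shares 21 nt with the Mir133a genes. Mir145a lies 1302 bp from Mir143 and was 26.9-fold lower. Mir27a, 80 bp from Mir23a, and Mirlet7c-1, 657 bp from Mir99a, were each 70.9-fold lower than that neighbour. However, Mirlet7c-1 shares 23 nt with Mirlet7c-2, so its read count is a lower bound. Mir99a had a log2 ratio of replicate 2 over replicate 1 of 0.76 and Mirlet7c-1 one of -0.16.

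A shared primary transcript was a hypothesis for replicate differences that run together among neighbours. Over 33 same-strand pairs within 10 kb, outside the Dlk1-Meg3 cluster and at 100 CPM or more, the mean absolute difference of log2 ratios was 0.27, against 0.34 in random pairings (one-sided permutation p = 0.02996). Without the Mir144 and Mir451a pair it was 0.28 over 32 pairs, against 0.28 (one-sided permutation p = 0.489). The result rests on that pair, so the hypothesis stays open.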
